A study of Natrinema gari with 11 samples.

How the data were processed

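RNA sequencing of Natrinema sp. J7-1, entered by the submitters under the organism name Natrinema gari, was taken from 11 libraries. Cultures had received mitomycin C at 1 µg/mL for 30 min, were washed and resuspended in fresh medium, and were sampled 0, 1, 4 and 9 h later. There were 2 libraries at 0 h, numbered replicates 2 and 3, and 3 at each of the other times. Total RNA had been extracted with Trizol, and the library kit and strand are not given in the sources used here.

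The counts are whole numbers that the authors deposited per library and that the file headers call unique reads. The submitters' processing notes name Bowtie2 for alignment, RSEM for quantification and edgeR for their own test, with versions not given in the sources used here. The FPKM values, per the file headers and checked here, equal reads scaled by coding length and by the library total, with a largest relative deviation of 1.05e-08. The deposited files also hold a percent column, the share of each gene covered by reads per the file headers, which was not used here. Genes with 0 reads are not listed, so a missing gene was read as 0; 141 of 3595 genes were missing from at least 1 file, and 3512 to 3585 were listed per library. Lines without a gene name, present in 6 files, held 0.0% of the reads. Coding lengths were multiples of 3 in 98.8% of the genes. No ribosomal or transfer RNA gene is listed, and the ribosomal protein list had 1 member, so these lists were not tested. No reference genome was used here, so gene names are those in the files.

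Libraries held between 15825903 and 19035825 counted reads. In simulated data of this depth, spread and design, with 3523 genes of which 200 were changed, the test recovered 1.49% of 1.5-fold, 11.9% of 2-fold and 68.2% of 4-fold changes for 1 h against 0 h, with 5 of 59 calls false. For 4 h against 1 h it recovered 1.49%, 23.9% and 83.3% (4 of 76 calls false), and for 9 h against 4 h 0%, 25.4% and 81.8% (4 of 75 calls false). Far more genes were called in the real data, 44.3%, 22.1% and 12.0% of those tested in these comparisons. The adjustment for many tests is less strict where more genes change, so recovery in the real data may have been higher than simulated. The real data had been fitted once before these simulations were written.

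Genes were tested in Python 3.11.15 and R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr with its defaults (3523 genes kept), 1 quasi-likelihood fit of all 11 libraries with a mean per time, and Benjamini-Hochberg adjusted p under 0.05. The standard error is the log2 fold change divided by the square root of F. CPM values are on plain library totals, whereas fold changes are on TMM-scaled totals, so a ratio of CPM need not equal the fold change. Comparisons were each later time against 0 h, 4 h against 1 h and 9 h against 4 h, with an F test across the 4 times. Gene lists were tested with camera of limma 3.58.1 on voom values, with its preset correlation of 0.01 between genes and adjustment over 95 pairs of 19 lists and 5 comparisons. Lists needed at least 5 measured members. Shares of reads were tested by exact permutation of the libraries among the times. For single genes named with 4 or fewer reads at 0 h, ratios against 0 h were given from counts with a 95% counting interval. Against 0 reads the ratio was a lower bound, with a floor of 3 reads in place of the 0. Other packages were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

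Tests, comparisons, 21 gene lists and the rule for naming genes were fixed before the data were examined. The rule named the SNJ2 genes ORF.1, ORF.4, ORF.7 and ORF.8, radA, ftsZ1 and ftsZ2 at every time. For each comparison with 0 h it added the 6 largest rises and 6 largest falls among called, annotated genes outside the proviruses, with a mean of at least 10 CPM in the higher group and every later library beyond every 0 h library. It also added up to 2 members with the smallest adjusted p for the 6 lists of lowest camera p, and, for the other comparisons, the 3 largest rises and falls. The meaning of annotated was made stricter after the first picks had been seen: names such as protein NJ7G_0089 no longer counted, which brought in copB and NJ7G_RS00135. List terms were edited, with 17 members taken out, after the values could be opened but before any chromosomal fold change was seen. The lists were found by words in gene names, and provirus genes were kept out of the others.

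Identifiers beginning ORF were taken as SNJ2 (24 genes), and those beginning CWS96 as SNJ1. Blocks are runs of identifier numbers, picked after values were seen, and gene order on the chromosome was not checked.

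Alternatives were DESeq2 1.42.0 with its own size factors, edgeR with median-of-ratios size factors, no filter, a filter of at least 10 CPM in 2 samples, provirus genes left out, replicate number as a block, a fit of the 2 times compared, a 2-fold minimum and each library left out in turn. Lists were also tested with fry, with an estimated correlation, with the stricter filter and with the block, and shares from FPKM or without the largest member. Fry tests a list against no change, whereas camera tests it against the other genes, so the 2 answer different questions. Where 0 h was left with 1 library, that lone sample was assumed to vary like the other groups. Chosen after seeing the data were 4 more alternatives: leaving out the provirus gene with the most reads at 0 h (ORF.10 for SNJ2, gp03 for SNJ1) from the shares, leaving out the abundant genes NJ7G_RS18915 and NJ7G_RS18045, leaving out the libraries numbered 3 at 1 h, 4 h and 9 h together, and removing the trend with coding length by loess. The loess fit of the last alternative also took out the level of each library. Replicate 1 at 0 h is not analysed here.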

Results

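Transcripts of the haloarchaeon Natrinema sp. J7-1 were followed at 0, 1, 4 and 9 h after a 30 min exposure to the DNA-damaging drug mitomycin C at 1 µg/mL, with 2 libraries at 0 h and 3 at each later time. The strain carries SNJ2, a provirus of the pleolipovirus family, and the series asks how DNA damage is signalled to it. SNJ2 genes made up 0.0364 ± 0.00416% of the reads at 0 h (mean ± SD, n = 2), 0.0418 ± 0.00671% at 1 h, 0.464 ± 0.0780% at 4 h and 6.92 ± 2.77% at 9 h (n = 3 each). The integrase gene of SNJ2, ORF.1, was 241.4-fold higher at 4 h than at 0 h, and the recombinase gene radA was already at 3041 ± 305 CPM at 1 h against 742 ± 80.7 CPM at 0 h. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2115 of 3523 tested genes (60.03%) differed among the 4 times at an adjusted p under 0.05. No untreated culture is part of the series used here, so the effect of the drug and the effect of time after the wash were not separable. The labels do not say whether replicates were separate cultures, so each p measures the spread between these samples, which may be technical. Calls of lists, genes and shares followed choices made before the data were examined, except where stated.

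The share of reads from SNJ2 differed among the 4 times (exact permutation p = 0.00026 over all 92400 assignments of the libraries). The share at 4 h was 12.8 times and at 9 h 190.3 times that at 0 h, and it rose 14.9 times from 4 h to 9 h, with single libraries at 9 h between 4.83% and 10.1%. Between 0 h and 1 h the ratio was 1.15 (exact permutation p = 0.4), and each of the other 4 pairs tested (4 h and 9 h against 0 h, 4 h against 1 h, 9 h against 4 h) gave an exact permutation p of 0.1, the smallest that groups of this size allow. One gene, ORF.10, held 67.8 ± 9.24% of the SNJ2 reads at 0 h, 52.4 ± 6.62% at 1 h and 0.884 ± 0.381% at 9 h. Without ORF.10, an alternative chosen after seeing the data, the SNJ2 share was 1.70 times that at 0 h at 1 h (exact permutation p = 0.1), 38.3 times at 4 h and 595.2 times at 9 h. It then rose 22.5 times from 1 h to 4 h and 15.6 times from 4 h to 9 h, against 11.1 and 14.9 times with ORF.10. A second set of 31 genes, taken here as the plasmid provirus SNJ1 from the prefix of their identifiers although the files do not name the virus, held 0.0401 ± 0.00279% of the reads at 0 h, 0.137 ± 0.0179% at 1 h, 3.12 ± 2.12% at 4 h and 2.94 ± 1.29% at 9 h. This SNJ1 share did not pass its test across the times (exact permutation p = 0.0612), with single libraries at 4 h of 0.893%, 5.10% and 3.37%. Each of these lay above both 0 h libraries, the higher of which held 0.0421%. The permutation tests compare raw means, so the wide spread among the 4 h libraries weakens them, including the pairwise test of 4 h against 0 h. Without replicate 1 at 4 h, the library of 0.893%, the exact permutation p was 0.00794. With all libraries, the pairwise ratios of the SNJ1 share were 3.41 for 1 h against 0 h (exact permutation p = 0.1), 77.7 for 4 h against 0 h (0.2, exact permutation), 73.2 for 9 h against 0 h (0.1, exact permutation), 22.8 for 4 h against 1 h (0.1, exact permutation) and 0.942 for 9 h against 4 h (1.0, exact permutation).

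**Figure D1:**
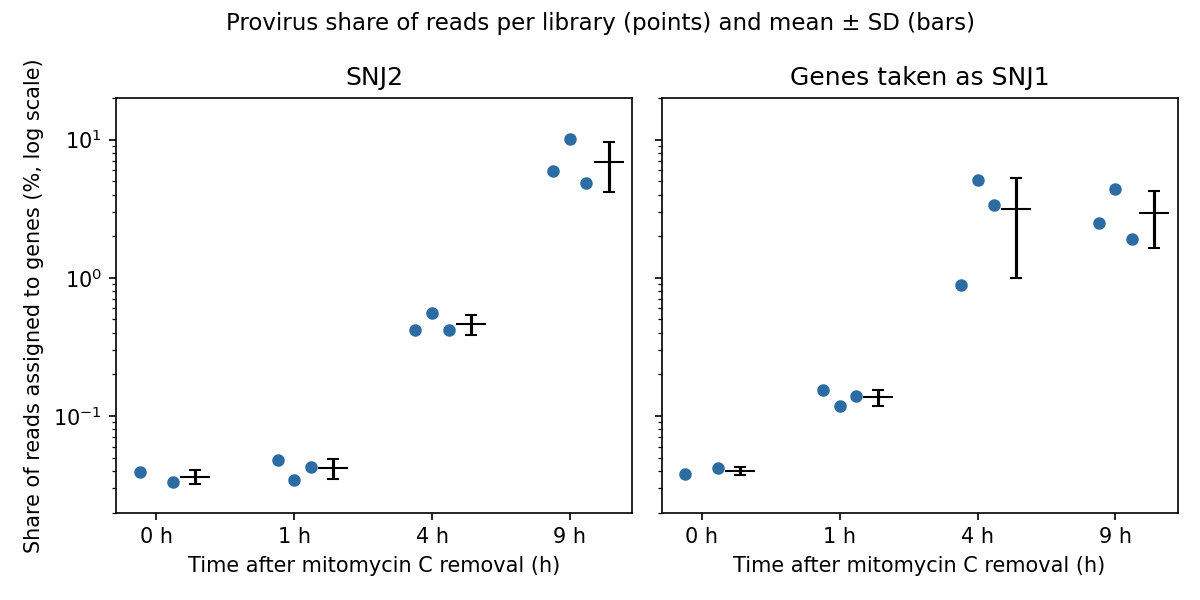
Share of reads (%, log axis) from SNJ2 and from the genes taken as SNJ1 against hours after the drug was washed out; points are single libraries and bars the mean ± SD of each time (n = 2 at 0 h, 3 at the others). SNJ2 climbed from 0.0364% at 0 h to 6.92% at 9 h, while the SNJ1 share stood at 3.12% at 4 h and 2.94% at 9 h.

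At 1 h the topoisomerase VI gene top6A (NJ7G_RS03630) rose 10.4-fold (log2 fold change 3.38, SE 0.393, n = 3 and 2, adjusted p = 8.45e-05). The gene radA (NJ7G_RS01400), for the strand-exchange protein of homologous recombination, rose by 2.00 (SE 0.291, adjusted p = 3.27e-04). The DNA ligase gene LIG1 (NJ7G_RS03315) rose by 1.73 (SE 0.183, adjusted p = 5.20e-05). The cell division gene NJ7G_RS17140, taken here as ftsZ1 because the files name it only ftsZ, fell by 0.96 (SE 0.203, adjusted p = 0.00293). The gene NJ7G_RS08935, taken here as ftsZ2 because its protein match in the files is named FtsZ 2, was not called (log2 fold change −0.50, SE 0.474, adjusted p = 0.403). Gains and losses were ranked among called, annotated genes outside the proviruses that reached at least 10 CPM in the higher group and whose libraries did not overlap between the times. At 1 h a PqqD family gene (NJ7G_RS14310) rose most among these, 13.9-fold (log2 3.79, SE 0.276). Others that rose were a zinc finger gene (NJ7G_RS02575, 3.63, SE 0.248, from 35.7 ± 5.69 to 455.6 ± 7.01 CPM) and queE (NJ7G_RS15200, 3.39, SE 0.506; 2.81 without replicate 1 at 1 h). The histidine degradation genes hutI (NJ7G_RS17290, 3.53, SE 0.464), hutH (NJ7G_RS17295, 3.43, SE 0.459) and hutG (NJ7G_RS17285, 3.41, SE 0.444) rose as well. The acyl-CoA dehydrogenase gene acd (NJ7G_RS14745) fell most among the genes so ranked (log2 −5.45, SE 0.286), from 842 ± 13.4 to 20.2 ± 3.27 CPM. Others that fell were dmsD (NJ7G_RS17365, −5.40, SE 0.751) and dmsC (NJ7G_RS17360, −4.53, SE 0.732) of a dimethyl sulfoxide reductase. The same ranking held a gene for a radical SAM-modified peptide (NJ7G_RS14180, −5.21, SE 0.298), and the cytochrome oxidase genes ctaB (NJ7G_RS12945, −4.77, SE 0.320) and coxB (NJ7G_RS12955, −4.36, SE 0.378).

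In all, 830 genes were higher and 731 lower at 1 h than at 0 h (44.3% of 3523), of which 686 and 553 by at least 2-fold. The count of higher genes was 519 without replicate 2 at 0 h and 402 without replicate 3 at 0 h, and 529 in a fit of these 2 times alone. Genes of few reads rose more often than they fell: among the 881 genes of lowest mean level, up to 11.4 CPM, 228 were higher and 58 lower.

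The SNJ2 provirus list, 24 genes, had 13 genes that rose, 0 that fell and 11 not called at 1 h (13 rose when adjusted over the list alone). Its median log2 fold change was 1.30 and its camera adjusted p = 0.0279, which was adjusted p = 0.927 with an estimated correlation and 0.0945 with the stricter filter of 10 CPM. Fry, which tests against no change, gave adjusted p = 0.0747. Most of these genes stood under 10 CPM at 0 h, and genes of few reads rose more often than they fell at 1 h. The list was not compared with other genes of its level, so a rise particular to SNJ2 at 1 h was not shown. ORF.19 rose by 2.63 (SE 0.346, adjusted p = 1.79e-04) and ORF.21 by 2.30 (SE 0.372, adjusted p = 6.33e-04). The integrase gene ORF.1 rose by 0.89 (SE 0.311, adjusted p = 0.0356, from 9.01 ± 0.927 to 17.52 ± 1.231 CPM). Its adjusted p was 0.0691 without replicate 2 at 0 h, 0.279 without replicate 3 at 0 h, 0.0740 without replicate 2 at 1 h and 0.0809 without replicate 3 at 1 h. It was 0.121 in the fit of 2 times and 0.105 without the libraries numbered 3 at 1 h, 4 h and 9 h, an alternative chosen after seeing the data. The winged helix regulator gene ORF.4 was not called (log2 fold change 0.29, adjusted p = 0.714; −0.59 without replicate 3 at 1 h and −0.64 without the libraries numbered 3). ORF.7 held 4 reads at 0 h and was not called (adjusted p = 0.113; ratio 4.13 by counts, 95% interval 1.43–16.3). It passed without replicate 1 at 1 h (log2 fold change 2.57, adjusted p = 0.0223) and in DESeq2 (adjusted p = 0.0493). The Orc1/Cdc6-type gene ORF.8 was not called either (log2 fold change 1.01, adjusted p = 0.0871). It passed without replicate 2 at 9 h (adjusted p = 0.0423), without replicate 1 at 1 h (adjusted p = 0.04998) and with replicate number as a block (adjusted p = 0.0323).

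Of the 31 genes taken as SNJ1, 10 rose, 0 fell and 21 were not called at 1 h (7 when adjusted over the list alone). The camera adjusted p = 0.0206 was adjusted p = 0.927 with an estimated correlation, and fry gave adjusted p = 0.190. Most of these genes also stood under 10 CPM at 0 h, and this list too was not compared with other genes of its level. The genes that rose were gp01, gp02, gp05, gp07 to gp11, gp22 and gp29, among them gp11 by 7.98-fold (SE 0.337 in log2, adjusted p = 6.78e-05) and gp10 by a log2 of 2.94 (SE 0.389, adjusted p = 1.89e-04). Within gp07 to gp11, a block picked after values were seen, each of the 5 genes rose, by 2.66 to 3.08, and gp07 carries a sigma-factor family name.

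**Figure D2:**
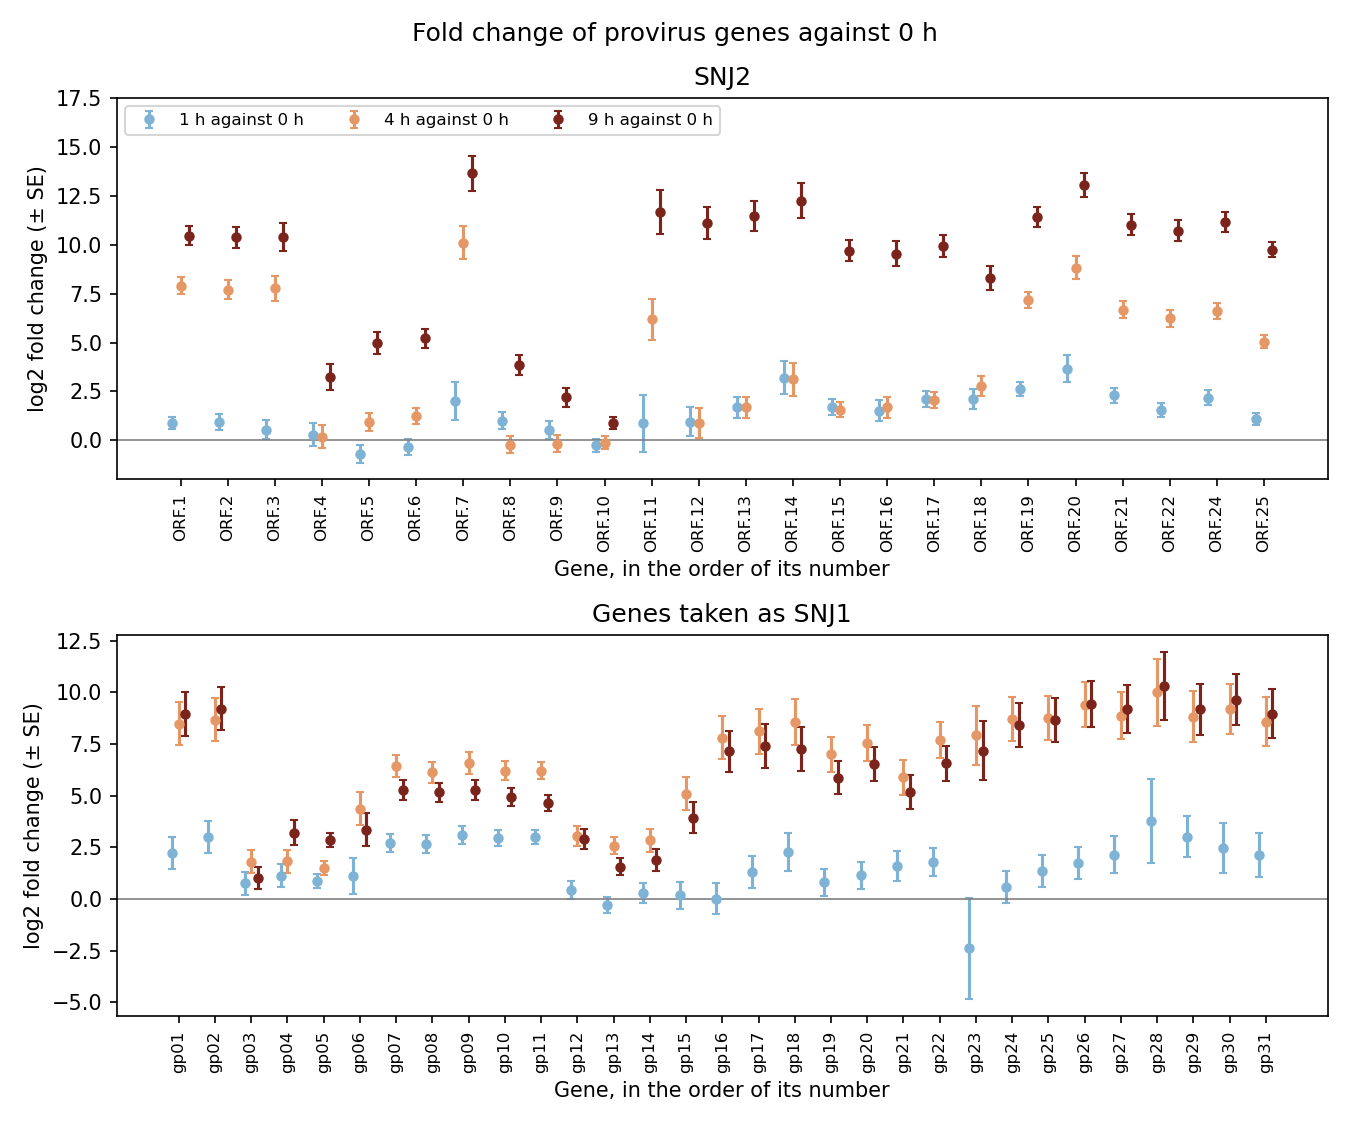
Log2 fold change against 0 h (± SE) of each gene of SNJ2 and of the genes taken as SNJ1 in number order, with 1 h, 4 h and 9 h in separate colours (n = 3 against 2 libraries). ORF.1 stood at 0.89, 7.92 and 10.45, while ORF.4 stood at 0.29 and 0.19 before it reached 3.23 at 9 h.

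Among the chromosomal lists at 1 h, the DNA replication list had 15 genes that rose, 3 that fell and 13 not called (15 and 3 when adjusted over the list alone). Its camera adjusted p = 0.0206 was adjusted p = 0.927 with an estimated correlation and 0.105 without replicate 2 at 1 h. In the DNA repair and recombination list 18 genes rose, 9 fell and 15 were not called (19 and 9 over the list alone), and camera did not call it (adjusted p = 0.163). Picked after values were seen, its risers included rad50 (NJ7G_RS13245, log2 2.03, adjusted p = 0.00377), mre11 (NJ7G_RS13250, 1.43), uvrB (NJ7G_RS02720, 1.19), uvrC (NJ7G_RS02755, 1.67) and udg (NJ7G_RS04105, 2.58), while recJ (NJ7G_RS01595, −1.06), mutS2 (NJ7G_RS02660, −1.25) and nurA (NJ7G_RS16365, −1.42) fell. Picked in the same way from replication, mcm (NJ7G_RS01035) rose by 2.24, top6B (NJ7G_RS03635) by 2.92 and replication protein A (NJ7G_RS17845) by 3.17.

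Sensor kinases and response regulators had 2 genes that rose, 9 that fell and 3 not called at 1 h (2 and 9 over the list alone; camera adjusted p = 0.0141, adjusted p = 0.486 with an estimated correlation, 0.0505 without replicate 2 at 0 h). Among these the PAS domain genes NJ7G_RS13865 and NJ7G_RS02370 had log2 fold changes of −2.68 (SE 0.270) and −2.08 (SE 0.230). Transposases and integrases had 13 genes that rose, 1 that fell and 13 not called (17 and 1 over the list alone; camera adjusted p = 0.00865, adjusted p = 0.486 with an estimated correlation, 0.529 with the stricter filter of 10 CPM). Whether copies of these elements share reads was not tested, so single members are uncertain. NJ7G_RS16530, with 3 reads at 0 h, was 17.8 times higher by counts (95% interval 5.89–88.2; log2 fold change 4.65 without replicate 2 at 0 h), and NJ7G_RS19030, with 0 reads at 0 h, at least 13.6-fold. Intervals and floors of this kind cover counting error alone, and reads amplified by PCR without molecular identifiers are not independent counts.

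The remaining lists were not called by camera at 1 h. Translation factors and aminoacyl-tRNA ligases had 11 genes that rose, 3 that fell and 23 not called (9 and 3 over the list alone; adjusted p = 0.0876), as leuS (NJ7G_RS15525) fell by 2.25. NJ7G_RS13755, named eIF-2B in one source and ribose 1,5-bisphosphate isomerase in another, fell by 2.01. Cell division and chromosome segregation genes had 1 up, 8 down and 8 not called (1 and 8 over the list alone; adjusted p = 0.146), the respiratory chain and ATP synthase list 25, 12 and 13 (26 and 12; adjusted p = 0.153). Central carbon metabolism had 4, 12 and 14 (5 and 12; adjusted p = 0.153), and chaperones and proteolysis 1, 7 and 20 (1 and 6; adjusted p = 0.270). Archaella, pili and chemotaxis genes had 4 up, 7 down and 12 not called (4 and 7 over the list alone; adjusted p = 0.295), RNA polymerase and general transcription factors 13, 6 and 7 (13 and 6; adjusted p = 0.342). ABC transporters had 32, 14 and 57 (32 and 14; adjusted p = 0.420), and defence, CRISPR-Cas and restriction genes 4, 1 and 14 (4 and 1; adjusted p = 0.423). Helix-turn-helix regulators had 30 up, 35 down and 78 not called (30 and 35 over the list alone; adjusted p = 0.520). There camera pointed down although the median was 0.02 and the mean 0.08. Nucleotide metabolism had 11 up, 9 down and 26 not called (11 and 9 over the list alone; adjusted p = 0.645). Oxidative stress and redox genes had 10, 3 and 14 (10 and 3; adjusted p = 0.662), and gas vesicle, surface and extracellular proteins 4, 5 and 10 (6 and 5; adjusted p = 0.733). Across the 5 comparisons camera called 22 of 95 pairs of list and comparison, and with an estimated correlation it called 0 of the 95, with 7 at an unadjusted p under 0.05 and a lowest adjusted p = 0.131.

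At 4 h the rises of the SNJ2 genes differed widely in size. The integrase gene ORF.1 rose 241.4-fold against 0 h (log2 fold change 7.92, SE 0.433, n = 3 and 2, adjusted p = 1.34e-06) to 2166 ± 424 CPM, and ORF.19 rose by 7.17 (SE 0.430). ORF.7 was 1146 times higher by counts (95% interval 448–4209), whereas ORF.4 (log2 fold change 0.19, adjusted p = 0.812) and ORF.8 (−0.22, adjusted p = 0.710) were not called. Of the 24 genes 18 rose, 0 fell and 6 were not called (18 rose over the list alone). The list had a median of 2.95 and a camera adjusted p = 3.06e-08, which was adjusted p = 0.486 with an estimated correlation. In blocks picked after values were seen, ORF.1 to ORF.3 rose by 7.71 to 7.92 and ORF.19 to ORF.25 by 5.05 to 7.17, except ORF.20, which had 2 reads at 0 h and was 507.9 times higher by counts (95% interval 140.4–4198). In the same reading 6 of the 7 genes of ORF.12 to ORF.18 rose, by 1.57 to 3.12, and ORF.12 was not called (log2 fold change 0.89, adjusted p = 0.355). The upper end of that range was ORF.14, which had 5 reads at 0 h. The 31 genes taken as SNJ1 rose without exception (31, 0 and 0; 31 over the list alone). They had a median of 7.55 and a camera adjusted p = 1.14e-15, which was adjusted p = 0.486 with an estimated correlation. Among them gp11 rose 73.6-fold (log2 6.20, SE 0.398), gp10 by 6.19 (SE 0.462), and gp24 to gp31, a block picked after values were seen, by 8.58 to 9.40, except gp28, which had 1 read at 0 h and was 1308 times higher by counts (95% interval 234.5–51700).

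On the chromosome at 4 h, radA (NJ7G_RS01400) stayed up by 1.81 (SE 0.289, adjusted p = 5.38e-04). NJ7G_RS17140, taken as ftsZ1, fell by 0.82 (SE 0.203, adjusted p = 0.00698). This call was lost without replicate 2 at 0 h (adjusted p = 0.0623), without replicate 3 at 0 h (0.0553) and without the libraries numbered 3 (0.0725). The gene ftsZ2 was not called (log2 fold change −0.54, adjusted p = 0.371). The zinc finger gene NJ7G_RS02575 rose 21.9-fold (log2 4.45, SE 0.259). The hut genes rose too, hutH (NJ7G_RS17295) by 4.04 (SE 0.475), hutI (NJ7G_RS17290) by 3.88 (SE 0.473) and hutG (NJ7G_RS17285) by 3.67 (SE 0.451). The transporter gene NJ7G_RS12475 rose by 3.58 (SE 0.655) and the substrate-binding protein gene NJ7G_RS09035 by 3.53 (SE 0.607). Among the genes ranked as at 1 h, the phenylacetate degradation gene paaA (NJ7G_RS08070) fell furthest and was 94.1-fold lower (log2 −6.56, SE 0.818). Of the same pathway, paaB (NJ7G_RS08075) fell by 6.20 (SE 0.855; log2 −5.54 without replicate 3 at 0 h) and paaC (NJ7G_RS08080) fell by 5.24 (SE 0.804). The ranking also held ctaB (NJ7G_RS12945, −5.89, SE 0.335), coxB (NJ7G_RS12955, −5.28, SE 0.397) and the metal-translocating P-type ATPase gene copB (NJ7G_RS12975, −4.82, SE 0.357). In all, 744 genes were higher and 820 lower at 4 h than at 0 h (44.4%), 594 and 621 of them by at least 2-fold. The higher count was 447 without replicate 3 at 0 h, and the lower count 507 without replicate 2 and 537 without replicate 3 at 0 h.

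Central carbon metabolism was lowered at 4 h (3 genes rose, 12 fell and 15 were not called; 3 and 14 over the list alone; camera adjusted p = 0.0279, adjusted p = 0.927 with an estimated correlation). This call was lost without replicate 2 at 0 h (0.0771), without replicate 3 at 4 h (0.101), without the libraries numbered 3 (0.0928) and with the 10 CPM filter (0.0754). Its members ppc (NJ7G_RS05430), for phosphoenolpyruvate carboxylase, and mct (NJ7G_RS13835), for a CoA transferase, had log2 fold changes of −2.12 (SE 0.262) and −1.89 (SE 0.264). Transposases and integrases had 18 genes that rose, 4 that fell and 5 not called at 4 h (18 and 4 over the list alone; camera adjusted p = 0.00306, adjusted p = 0.486 with an estimated correlation, 0.508 with the 10 CPM filter). NJ7G_RS16530 was 38.1 times higher by counts (95% interval 12.8–187; log2 fold change 5.84 without replicate 2 at 0 h), and NJ7G_RS18820, with 0 reads at 0 h, at least 23.2-fold. Sensor kinases had 1 gene up, 8 down and 5 not called (3 and 9 over the list alone; adjusted p = 0.0764), and NJ7G_RS13865 fell by 2.43 (SE 0.269) while NJ7G_RS04970 fell by 2.15 (SE 0.285). Cell division and chromosome segregation genes had 2 up, 6 down and 9 not called (2 and 6 over the list alone; adjusted p = 0.0702), and the tubulin-like gene cetZ (NJ7G_RS04125) fell by 1.22 (SE 0.199). NJ7G_RS00120 fell by 3.02 (SE 0.226). It entered that list through the name cell division cycle protein 48, an ATPase family that is not specific to division, and its identifier number falls among those of phage-tail-like genes. DNA repair had 13 up, 11 down and 18 not called (14 and 12 over the list alone; adjusted p = 0.381), and DNA replication 9, 4 and 18 (9 and 4; adjusted p = 0.295). In the respiratory list 15 rose, 12 fell and 23 were not called (17 and 14 over the list alone), with a median of 0.21 but a mean of −0.20 (adjusted p = 0.768).

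At 9 h each of the 24 SNJ2 genes had risen against 0 h, the integrase gene ORF.1 by 1403-fold (log2 fold change 10.45, SE 0.480, n = 3 and 2, adjusted p = 8.67e-08) to 15587 ± 5885 CPM. ORF.25 rose 857.5-fold (log2 9.74, SE 0.381, adjusted p = 5.53e-08; 9.12 with the length trend removed), ORF.4 by 3.23 (SE 0.659, adjusted p = 0.00281; 2.62 with that trend removed) and ORF.8 by 3.84 (SE 0.510, adjusted p = 1.88e-04), and ORF.7 was 14180 times higher by counts (95% interval 5537–52040). The list (24, 0 and 0; 24 over the list alone) had a median of 10.39 and a camera adjusted p = 4.89e-23, which was adjusted p = 0.303 with an estimated correlation. In blocks picked after values were seen, ORF.12 to ORF.18 rose by 8.31 to 12.26 and ORF.19 to ORF.25 by 9.74 to 11.43, but ORF.8 to ORF.10 by 0.89 to 3.84. ORF.20, left out of the range of its block for its 2 reads at 0 h, was 9645 times higher by counts (95% interval 2670–79640). ORF.14, at the upper end of its block, had 5 reads at 0 h. ORF.10, at the lower end of its block, passed only narrowly (log2 fold change 0.89, SE 0.330, adjusted p = 0.04997). It carries the same pilin family name as the chromosomal gene NJ7G_RS03140, and shared sequence was not tested. Of the genes taken as SNJ1, 30 rose, 0 fell and 1 was not called (30 over the list alone), with a median of 6.54 and a camera adjusted p = 1.71e-15, which was adjusted p = 0.486 with an estimated correlation. Among these gp10 rose by 4.93 (SE 0.433) and gp11 by 4.64 (SE 0.367).

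On the chromosome at 9 h, radA (NJ7G_RS01400) was still up by 1.75 (SE 0.288, adjusted p = 7.69e-04). NJ7G_RS17140, taken as ftsZ1, fell by 0.73 (SE 0.203, adjusted p = 0.0148). That call was lost without replicate 2 at 0 h (adjusted p = 0.0941), without replicate 3 at 0 h (0.0992), without replicate 3 at 9 h (0.0515) and without the libraries numbered 3 (0.103). NJ7G_RS08935, taken as ftsZ2, was not called (log2 fold change 0.53, adjusted p = 0.401), but was 0.95 without replicate 2 at 9 h (adjusted p = 0.0325). The largest rises among the genes ranked as at 1 h were those of a hydrolase gene (NJ7G_RS11240, 3.90, SE 0.344), a secY-type translocase gene (NJ7G_RS15465, 3.88, SE 0.510) and a MarR family regulator gene (NJ7G_RS10735, 3.76, SE 0.377; 4.496 without replicate 3 at 0 h). The small heat shock gene HSP20 (NJ7G_RS15135) rose by 3.57 (SE 0.380), from 88.1 ± 11.7 to 1246 ± 196 CPM. An AbrB-type gene (NJ7G_RS02475, 3.40, SE 0.429; 2.77 with the length trend removed) and an oxidoreductase gene (NJ7G_RS05915, 3.29, SE 0.650) followed. Falls in the same ranking were largest for dmsC (NJ7G_RS17360, −6.47, SE 0.794), dmsD (NJ7G_RS17365, −6.37, SE 0.782) and dmsB (NJ7G_RS17355, −6.26, SE 0.794), which were −7.47, −7.53 and −7.13 without replicate 1 at 9 h. Then followed ctaB (NJ7G_RS12945, −5.78, SE 0.333), the peptide gene NJ7G_RS14180 (−5.43, SE 0.300) and coxB (NJ7G_RS12955, −5.39, SE 0.397). In all, 676 genes were higher and 753 lower at 9 h than at 0 h (40.6%), 558 and 518 of them by at least 2-fold. The higher count was 422 without replicate 2 and 370 without replicate 3 at 0 h, and the lower count 439 and 447 without the same libraries, and 491 without the libraries numbered 3.

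Sensor kinases were lowered again at 9 h (1 rose, 5 fell and 8 were not called; 2 and 6 over the list alone). Their camera adjusted p = 0.0234 was adjusted p = 0.486 with an estimated correlation, 0.0840 without replicate 2 at 0 h and 0.0650 with the 10 CPM filter. Of their members NJ7G_RS13865 fell by 2.95 (SE 0.272) while NJ7G_RS02370 fell by 2.23 (SE 0.230). Transposases and integrases had 16 genes that rose, 1 that fell and 10 not called (16 and 1 over the list alone; camera adjusted p = 0.00233, adjusted p = 0.486 with an estimated correlation, 0.247 with the 10 CPM filter). NJ7G_RS16530 was 15.8 times higher by counts (95% interval 5.23–78.1; log2 fold change 4.49 without replicate 2 at 0 h) and NJ7G_RS18820 at least 13.4-fold. Cell division and chromosome segregation genes had 2 up, 6 down and 9 not called (2 and 7 over the list alone; adjusted p = 0.142), and a second cetZ gene (NJ7G_RS17270) fell by 1.72 (SE 0.214). NJ7G_RS00120, the Cdc48-type ATPase gene numbered among the tail-like genes, fell by 2.60 (SE 0.223). RNA polymerase and general transcription factors had 6 up, 3 down and 17 not called (6 and 3 over the list alone; adjusted p = 0.295). There, tfb (NJ7G_RS04140) fell by 1.94 (SE 0.334) and nusA (NJ7G_RS00820) rose by 1.40 (SE 0.348, adjusted p = 0.00826). The nusA value was 2.02 without replicate 2 at 0 h, 1.05 without replicate 3 at 0 h (adjusted p = 0.0826) and 1.00 with the length trend removed (adjusted p = 0.0549). DNA repair had 10 up, 15 down and 17 not called (10 and 15 over the list alone; adjusted p = 0.788), where camera pointed down with a median of 0.02 and a mean of −0.03. Chaperones and proteolysis had 7 up, 8 down and 13 not called (7 and 10 over the list alone; adjusted p = 0.682), and the respiratory list 14, 15 and 21 (14 and 15; adjusted p = 0.693), with a median of 0.19, a mean of −0.44 and a camera direction of down.

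**Figure D3:**
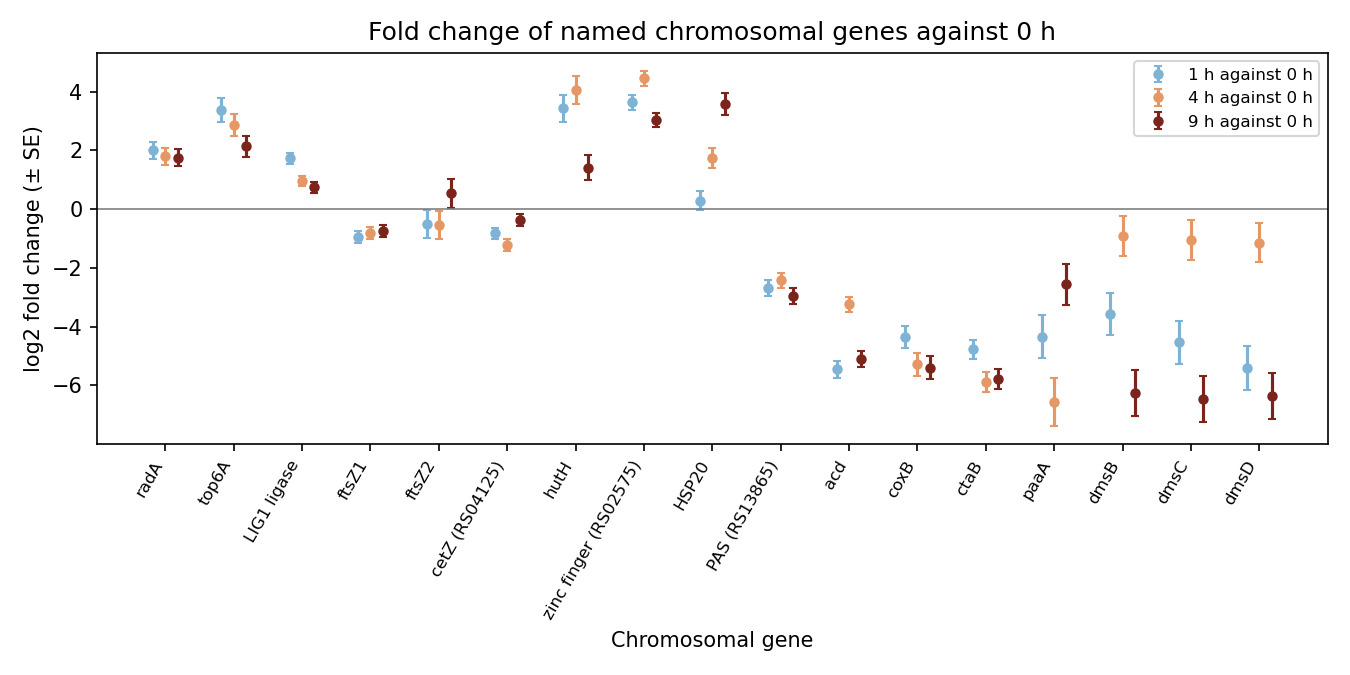
Log2 fold change against 0 h (± SE) of 17 chromosomal genes at 1 h, 4 h and 9 h (n = 3 against 2 libraries). The gene radA stood at 2.00, 1.81 and 1.75, HSP20 reached 3.57 at 9 h, and dmsC stood at −4.53 at 1 h and −6.47 at 9 h.

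From 1 h to 4 h the integrase gene ORF.1 rose 129.8-fold (log2 fold change 7.02, SE 0.344, n = 3 each, adjusted p = 7.19e-07) and ORF.7 by 8.08, while ORF.4 was not called (−0.10; 0.87 without replicate 3 at 1 h and 0.68 without the libraries numbered 3). ORF.8 fell by 1.23 (SE 0.399, adjusted p = 0.0471), a call lost in 15 alternatives. Its adjusted p was 0.0802 and 0.0933 without replicates 2 and 3 at 0 h, and 0.0878 and 0.1695 without replicates 2 and 3 at 1 h. It was 0.1745, 0.131 and 0.0688 without replicates 1, 2 and 3 at 4 h, and 0.0605 without replicate 3 at 9 h. SNJ2 had 13 genes that rose, 1 that fell (ORF.8) and 10 not called (13 and 1 over the list alone; camera adjusted p = 4.98e-10, adjusted p = 0.486 with an estimated correlation). The genes taken as SNJ1 had 28, 0 and 3 (28 over the list alone; camera adjusted p = 1.54e-25, adjusted p = 0.486 with an estimated correlation). In blocks picked after values were seen, ORF.19 to ORF.25 rose by 3.96 to 5.17, but none of the 7 genes ORF.12 to ORF.18 was called. On the chromosome dmsD (NJ7G_RS17365) rose by 4.26 (SE 0.692), dmsC (NJ7G_RS17360) by 3.48 (SE 0.674) and trpC (NJ7G_RS17370) of tryptophan synthesis by 3.32 (SE 0.471). The tail sheath gene NJ7G_RS00155 fell by 4.26 (SE 0.583), and the tail protein genes NJ7G_RS00150 and NJ7G_RS00135 stood at −3.95 (SE 0.557) and −3.83 (SE 0.508). Without replicate 2 at 1 h the 3 genes were at −3.41, −3.08 and −3.13. The genes radA (−0.19, adjusted p = 0.618), ftsZ1 (0.14) and ftsZ2 (−0.04) were not called.

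Between 1 h and 4 h, 329 genes were higher and 449 lower (22.1%), 189 and 290 of them by at least 2-fold. The higher count was 155 without the libraries numbered 3. The lower count was 299 without replicate 3 at 0 h, 251 without replicate 2 at 1 h, 190 without replicate 1 at 4 h and 209 without replicate 3 at 4 h. It was 253 in the fit of 2 times and 121 without the libraries numbered 3. ABC transporters were lowered (3 rose, 27 fell and 73 were not called; 5 and 32 over the list alone; camera adjusted p = 0.00529, adjusted p = 0.600 with an estimated correlation). So was the respiratory list (2, 9 and 39; 2 and 9 over the list alone; camera adjusted p = 0.0115, adjusted p = 0.927 with an estimated correlation, 0.108 without replicate 2 at 1 h, 0.0529 with fry). DNA replication was lowered (0, 6 and 25; 0 and 6 over the list alone; camera adjusted p = 0.0168, adjusted p = 0.927 with an estimated correlation, 0.266 without replicate 2 at 1 h, 0.0729 without replicate 3 at 4 h). Chaperones and proteolysis were raised (7, 3 and 18; 7 and 3 over the list alone; camera adjusted p = 0.0168, adjusted p = 0.927 with an estimated correlation, 0.144 without replicate 1 at 1 h, 0.0788 without replicate 1 at 4 h). One of the 7 was dmsD, whose TorD-type chaperone serves a single class of enzymes. Nucleotide metabolism was lowered (1, 10 and 35; 1 and 10 over the list alone; camera adjusted p = 0.0482, adjusted p = 0.486 with an estimated correlation). Leaving out libraries ended this call without replicate 2 (0.0840) or 3 (0.0905) at 0 h, replicate 1 (0.0570), 2 (0.147) or 3 (0.0753) at 1 h, replicate 3 at 4 h (0.136), and replicate 2 (0.0556) or 3 (0.0524) at 9 h. It also ended without the 2 abundant genes (0.0697), without the libraries numbered 3 (0.106) and with the 10 CPM filter (0.0754).

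From 4 h to 9 h each SNJ2 gene rose (24, 0 and 0; 24 over the list alone), with a median of 4.30 and a camera adjusted p = 7.20e-40, which was adjusted p = 0.131 with an estimated correlation. ORF.1 rose 5.81-fold (log2 fold change 2.54, SE 0.279, n = 3 each, adjusted p = 1.79e-04). ORF.4 rose by 3.04 (SE 0.553, adjusted p = 0.00431), ORF.7 by 3.54 and ORF.8 by 4.05 (adjusted p = 1.55e-04). ORF.12 to ORF.18, a block picked after values were seen, rose by 5.54 to 10.24. Of the genes taken as SNJ1, 1 rose, 3 fell and 27 were not called (1 and 4 over the list alone; camera adjusted p = 0.295). The permease gene NJ7G_RS09770 rose by 4.11 (SE 0.604), paaA (NJ7G_RS08070) by 3.99 (SE 0.726; adjusted p = 0.0679 without the libraries numbered 3) and the hydrolase gene NJ7G_RS11240 by 3.88 (SE 0.290). Falls among the genes ranked as at 1 h were largest for dmsC (NJ7G_RS17360, −5.42, SE 0.739), dmsB (NJ7G_RS17355, −5.36, SE 0.744) and dmsD (NJ7G_RS17365, −5.23, SE 0.725), which were −6.42, −6.23 and −6.39 without replicate 1 at 9 h. The genes radA (−0.05, adjusted p = 0.922), ftsZ1 (0.09) and ftsZ2 (1.08, adjusted p = 0.130; 1.49 with adjusted p = 0.00471 without replicate 2 at 9 h) were not called.

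Between 4 h and 9 h, 222 genes were higher and 202 lower (12.035%), 171 and 114 of them by at least 2-fold. The higher count was 90, 127 and 124 without replicates 1, 2 and 3 at 4 h, and 116 and 130 without replicates 1 and 3 at 9 h. It was 63 without the libraries numbered 3, and 347 in DESeq2. The lower count was 122 and 133 without replicates 1 and 2 at 4 h, and 121 and 111 without replicates 1 and 3 at 9 h. It was 66 without the libraries numbered 3, 318 in DESeq2 and 319 with the length trend removed. DNA repair and recombination was lowered (0, 8 and 34; 1 and 10 over the list alone; camera adjusted p = 0.00807, adjusted p = 0.927 with an estimated correlation). Among its members, picked after values were seen, uvrA (NJ7G_RS10180) fell by 1.44 and uvrB (NJ7G_RS02720) fell by 0.97. The respiratory list (1, 4 and 45; 0 and 0 over the list alone) was not called (adjusted p = 0.0506).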

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

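The counts of called genes depended on single libraries. With each library left out in turn, genes higher at 1h than 0h ranged from 402 to 871 and genes lower from 529 to 776. Genes higher at 4h than 0h ranged from 447 to 859 and lower from 507 to 870, and genes higher at 9h than 0h from 370 to 786 and lower from 439 to 817. Between 4h and 1h the ranges were 222 to 383 higher and 190 to 479 lower, and between 9h and 4h 90 to 296 and 111 to 257. Genes that differ among the 4 times ranged from 1631 to 2247, and calls of gene lists by camera from 18 to 28. The lowest counts against 0 h came without replicate 3 at 0 h for the rises at 1 h, 4 h and 9 h, and without replicate 2 at 0 h for the falls at 4 h and 9 h. Leaving out a library also lowers the number of samples.

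Among the other alternatives, genes higher at 1h than 0h were 529 with only the 2 times compared in the fit. Genes lower at 9h than 0h were 491 without the libraries numbered 3, chosen after seeing the data. Between 4h and 1h a 2-fold minimum gave 189 higher and 290 lower, the fit of 2 times 253 lower, and the libraries numbered 3 left out 155 and 121. Between 9h and 4h DESeq2 gave 347 higher and 318 lower, the 2-fold minimum 114 lower, the libraries numbered 3 left out 63 and 66, and removal of the length trend 319 lower. The cause was not tested, except that the 2-fold minimum calls fewer genes by construction. Of 15 pairs of libraries sharing a replicate number, correlations after removing the mean of each time ran from −0.278 to 0.538, with 6 over 0.1. The highest of these, 0.386 to 0.538, were among the libraries numbered 3. Pairs of different number ran from −0.445 to 0.403 (replicate 1 at 1 h with replicate 2 at 9 h). Medians were 0.009 for the same number and −0.049 for different numbers. With replicate number as a block the counts were 759 and 733, 730 and 824, 666 and 742, 350 and 435, and 205 and 223, in the order of the comparisons, with 2100 across the times.

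Camera with an estimated correlation called 0 lists against 22, the stricter filter 16 and the block 25. Fry, which tests against no change rather than against the other genes, called 25. Of 374 recalculated values of the 22 called lists, those of fry included, 321 stayed on their side of the threshold and 53 did not. Of 2421 recalculated values of 117 results for named genes, 2383 stayed, 31 fell short and 7 newly passed, in 10 results. Reversals of a called value were 0 in both sets. The share of reads from SNJ2 at 9 h ranged from 5.35% to 7.97% and that of the genes taken as SNJ1 from 2.21% to 3.45% with single libraries left out. Without the member with the most counts at 0 h, the SNJ2 provirus share of counts at 9 h was 6.87% (exact permutation p = 6.494e-05) and the SNJ1 plasmid provirus pHH205 share of counts 2.92% (exact permutation p = 0.0623). The SNJ1 share passed its test with the 2 abundant genes left out (3.52%, exact permutation p = 0.0321) and without replicate 1 at 4 h (exact permutation p = 0.00794). A denominator with ribosomal RNA genes was not run, as no such genes are listed.

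Genes of few reads had lower values at 0 h than later. Depth does not account for this, as the 0 h libraries held 18305210 and 16989364 reads and the later ones 15825903 to 19035825. The cause was not tested. The 5th percentile of FPKM was 0.569 and 0.730 at 0 h and 1.25 to 3.29 in the later libraries. Removing the length trend moved the median of all genes at 1 h from 0.17 to 0.05 and at 9 h from 0.07 to −0.10. The loess fit also took out the level of each library, so this move does not by itself show an effect of length.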

Other observations

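Several runs of chromosomal identifier numbers, picked after values were seen, had most of their genes called in 1 direction. In NJ7G_RS00115 to NJ7G_RS00160, 10 genes that include tail sheath and tail protein genes, each gene fell between 1 h and 4 h (log2 −4.35 to −1.50), and 5 of the 10 rose again from 4 h to 9 h. In NJ7G_RS12930 to NJ7G_RS12980, which holds ctaB, coxB and copB, 10 of 11 genes were lower at 1 h, 4 h and 9 h than at 0 h, with medians of −3.66, −4.82 and −4.52. The run NJ7G_RS08040 to NJ7G_RS08095, which holds paaA to paaC, had 10, 11 and 8 of 12 genes lower at these times, and 7 rose from 4 h to 9 h. The 3 tryptophan genes NJ7G_RS17370 to NJ7G_RS17380 fell at 1 h, were not called at 4 h and were lower at 9 h than at 0 h. A surface glycoprotein gene, NJ7G_RS06500, held 4.42 ± 0.513% of the reads at 0 h (n = 2), 16.2 ± 3.41% at 1 h, 15.7 ± 3.28% at 4 h and 9.50 ± 2.09% at 9 h (n = 3 each).

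Single genes picked after values were seen add to this. The thermosome genes NJ7G_RS11150, NJ7G_RS00385 and NJ7G_RS16960, for chaperonin subunits, rose at 9 h by 2.46, 1.74 and 1.64. The toxin-type gene vapC (NJ7G_RS02470) rose by 2.48, 3.11 and 3.23 at 1 h, 4 h and 9 h, dps (NJ7G_RS16670), for a DNA-binding protein of starved cells, fell by 2.89 at 9 h, and the catalase-peroxidase gene katG (NJ7G_RS14665) fell by 2.73 from 1 h to 4 h. The gene NJ7G_RS18915, of 312 bases, held between 1.76% and 24.1% of the reads of single libraries, and NJ7G_RS18045, of 560 bases, between 1.23% and 8.57%. The share of NJ7G_RS18915 was highest in the libraries numbered 3 at 1 h, 4 h and 9 h (15.75%, 24.12% and 21.17%). The other libraries of these times held 1.76% to 9.20%. At 0 h replicate 3 held less than replicate 2 (7.03% against 10.02%).

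Predictions for the transposases were written before their tests, but after the rise of genes of few reads had been seen. The tests on dmsA to dmsD and on SNJ1 at 4 h were chosen only after the results had been seen. Apart from fewer cells with an active SNJ1, no biological explanation was tested.

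Among 100 random groupings of the 11 libraries, the real one included, only the real one reached its count of 2115 genes differing among the times. The highest other gave 1058, and 100 groupings can give no smaller share than 1 of 100. The groupings treat the libraries as independent, which the labels do not settle, so chance differences between cultures were not addressed. For 4 h against 1 h, in fits of those 6 libraries alone rather than of all 11, 1 of the 10 splits was as high as the real one (564 genes against a highest other of 0), and for 9 h against 4 h also 1 of 10 (563 against 0). In both cases 10 splits are too few for a share under 0.05.

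The rise of transposases and integrases may be what genes of few reads do. Among 10000 random lists of 27 genes matched on their level at 0 h, the median of the real list stood at percentile 63.6 at 1 h (1.65 against a random median of 1.56, 0.91–2.12), 93.6 at 4 h (1.98 against 1.42, 0.77–2.06) and 68.6 at 9 h (1.86 against 1.71, 1.06–2.30). At each of these times the list stood below percentile 95 of the matched lists. Provirus genes were not kept out of the random lists. The rises of those genes may have raised the random medians and lowered these percentiles. An even background of reads, such as genomic DNA, would give similar reads per kb. Over 172 genes of few reads at 0 h the quartile ratio at 1 h was 4.89, against 1.22–1.33 from counting alone. An even background with counting error alone would thus not give this ratio. Uneven coverage, or genes that rose at 1 h on top of a background, could widen it too, so a background as part of the rise remains open.

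The genes dmsA to dmsD fell at 1 h, were not called against 0 h at 4 h, and fell again at 9 h, with dmsA (NJ7G_RS17350) at 3.01% of the reads at 0 h, 0.365 ± 0.197% at 1 h, 1.51 ± 0.953% at 4 h and 0.0841 ± 0.0440% at 9 h. Libraries of 0 h carrying a 4 h label could give this, but the lowest SNJ2 share at 4 h was 10.6 times the highest at 0 h, which argues against it. A change in the share taken by abundant genes could too. The 57 most abundant genes held 50.35 to 61.49% of the reads of each library at 1 h and 4 h. Shares this alike are too close to give a change of the size seen. With these genes left out of the totals, the median log2 fold change of dmsA to dmsD from 1 h to 4 h was 3.02 (2.54 to 3.37 with single libraries left out), against 3.017 on all reads. Given those shares the value could have moved only slightly, so leaving the genes out adds no separate support.

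Replicate 1 at 4 h held 0.893% of its reads in the genes taken as SNJ1, against 5.10% and 3.37% in the other two. RNA of an earlier time mixed into this library would also lower SNJ2, yet its SNJ2 share was 0.859 times the mean of the others, which argues against it. If fewer cells had an active SNJ1, genes called at 1 h and the others would fall short alike. The 21 other genes fell short 2.87 times as much as the 10 genes called at 1 h (6.11 against 2.13), but with the genes of each set resampled 10000 times this ratio of medians ran from 0.5247 to 4.809 (95% range). The range holds values under and over 1.5, the bound set for the test, which leaves this explanation open.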
